A study of Mus musculus with 3 samples.

How the data were processed

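Array comparative genomic hybridisation was used on 3 neurosphere lines, which are free-floating cultures of tumour cells, grown from mouse gliomas that had come back under inhibition of the receptor CSF1R. Per the labels, the lines were taken at passages 2 to 3, neurosphere DNA was labelled with Cy5, and mouse liver DNA was labelled with Cy3 on the same array, with each liver carrying the animal number of its line. The 3 lines form 1 group. Line 1 has its own animal number, and lines 2 and 3 share another and the same liver label. All 3 arrays lay on 1 slide with no dye swap, so no batch could be compared and any effect of dye or slide is common to the 3 arrays.

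Per the file headers, the authors' spot intensity values came from Agilent Feature Extraction 10.7.3.1 and are background-subtracted, spatially and multiplicatively detrended and linearly dye-normalised. The deposited scanner files also give a log10 ratio of Cy5 over Cy3. The deposited value table holds log10 values with column medians of 0.000435, -0.00146 and -0.00271 for lines 1, 2 and 3. Set against the scanner ratios, its columns correlated at 0.867, 0.844 and 0.884 with slopes of 1.00, 1.01 and 0.998, which settles direction and scale. How it was centred, and which correction lies behind the difference, is not given in the sources used here. The arrays held 180880 spots, of which 6575 were controls. Spots with an outlier mark were left out, and averaging spots of the same probe left 170305 probes, 161460 on autosomes, 8723 on X and 122 on Y, with a median spacing of 10878 base pairs. A gene name stood beside 66.9% of probes. Names are those of the array's design. Coordinates are those of the file headers (mm9), and exon, intron and untranslated region annotation of that build was not used here. A table of GRCm38.p6 gene names served for synonyms and gene order only.

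For each probe, log2 of Cy5 over Cy3 was computed from the deposited processed intensities and centred on the autosomal median, so that a positive log2 value is a higher level in the line than in liver. A change from 2 copies to 3 in every cell would give 0.585, and a change from 2 to 1 would give -1. Each chromosome was divided into segments by penalised least squares (PELT), with a penalty of 10 times log(n), segments of at least 10 probes, and calls at an absolute mean of at least 0.2. Intervals are 95% intervals from blocks of 10 neighbouring probes, or from single probes in regions too short for blocks, and cover probe error within that array only. Chance calls came from 20 permutations of probe order within chromosomes, which remove any shift shared by neighbouring probes. Changes of known size were planted 100 times per size and line to measure detection. Whole chromosomes were compared by medians and an exact sign flip test. Means of genes with at least 3 probes were tested against 0 with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg) in R 4.3.3, and lists of genes with fry of the same package, which asks whether a list moves one way on balance. Probe values were reassigned to genes 20 times, with the values of the 3 arrays kept together. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

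Replicate p-values measure only the spread between these 3 lines, 2 of which share an animal number and are counted as separate samples. On simulated data with independent probe noise, the segmentation recovered 10 of 10 planted segments, all of the same length and size. It made 0 calls in the series without one. For the gene test across the 3 lines, with 9430 simulated genes, limma recovered 79 of 100 genes shifted by 0.5 and 27 of 100 shifted by 0.25, and called 2 unchanged genes. The simulated noise was independent between lines and held no probe or dye effect shared by the arrays. The 2 calls therefore do not measure errors on the real arrays, where reassigned probes gave a median of 2074.5 genes past the threshold.

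The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule named (a) 17 genes whatever their value, among them Csf1r, Igf1r, Igf1, Pik3ca, Pdgfra, Pdgfb, Egfr, Cdkn2a, Trp53, Nf1, Rb1, Myc, Mdm2, Cdk4, Cdk6 and Met; (b) list members in a called region or past the limma threshold, up to 25; (c) up to 10 genes per line in called regions under 3 Mb, which gave 0 genes; and (d) up to 10 genes above and 10 below 0 with the largest means among those past the limma threshold with 1 sign in all lines, at most 2 per chromosome. Results that need 2 of the genes taken by the rule are not reported here. Of the 17 genes, 15 had a probe of their own name, and Myc and Cdk4 were read from the probes around named neighbours. The 9 lists cover IGF1R, PI3 kinase, AKT and mTOR, receptor tyrosine kinases, cell cycle and p53, glioma drivers and lineage, RAS and MAPK, CSF1R and interleukin 4, drug efflux, DNA repair and sex chromosomes. A list of antigen receptor genes matched 0 names on the array and was not used. Other settings covered background correction, loess, centring, the value table, dim probes, local GC, segmentation settings, left-out lines and the animal as the unit. Segmentation at a penalty of 2 times log(n) with at least 5 probes, correction for local gene number, windows of 500 kb on each side of a gene, and comparisons of arrays within a dye were added after the data were seen.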

Results

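Copy number along the genome was measured in 3 neurosphere lines from gliomas that regrew under inhibition of CSF1R, the receptor that macrophages and microglia need for survival. Each line was set against mouse liver DNA, so that the ratio shows parts of the genome gained or lost in the tumour cells. The spread of differences between neighbouring probes was 0.384 in line 1, 0.232 in line 2 and 0.237 in line 3 (log2). For liver DNA, 96.3%, 98.5% and 99.1% of probes were well above background in lines 1, 2 and 3, and for line DNA 99.02% to 99.42%. No spot was saturated. The number of arrays limits the precision of every value over lines, and no locus in a line has a replicate.

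With the main settings, no gain or loss was called in any of the 3 lines. The segment farthest from 0 had an absolute mean of 0.096 in line 1, 0.14 in line 2 and 0.070 in line 3, below the call threshold of 0.2. In line 2 it was the distal part of chromosome 15, from 72803967 to 103460314 (2545 probes), with a mean of 0.14 (95% interval 0.12 to 0.15). The same stretch averaged 0.096 in line 3 (0.081 to 0.11) and 0.023 in line 1 (0.0051 to 0.041). In line 2 it fell to 0.097 after correction for local gene number and to 0.075 in the authors' value table. The rest of chromosome 15 averaged 0.021 in line 2, and 0.052 and 0.0495 under those settings. Local GC correction gave 0.11 for the distal part in line 2, normexp 0.15 and loess 0.14. Permuted probes gave 0 calls in 20 permutations of each array. Planted gains of 0.5 over 250 probes, about 2.72 Mb, were recovered 98, 100 and 100 times of 100 in lines 1, 2 and 3. Planted losses of -1 over 25 probes were recovered 8, 100 and 98 times. Losses of -0.5 over 10 probes were recovered 0 times in each line, so events of that size were not detectable with these settings.

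**Figure D1:**
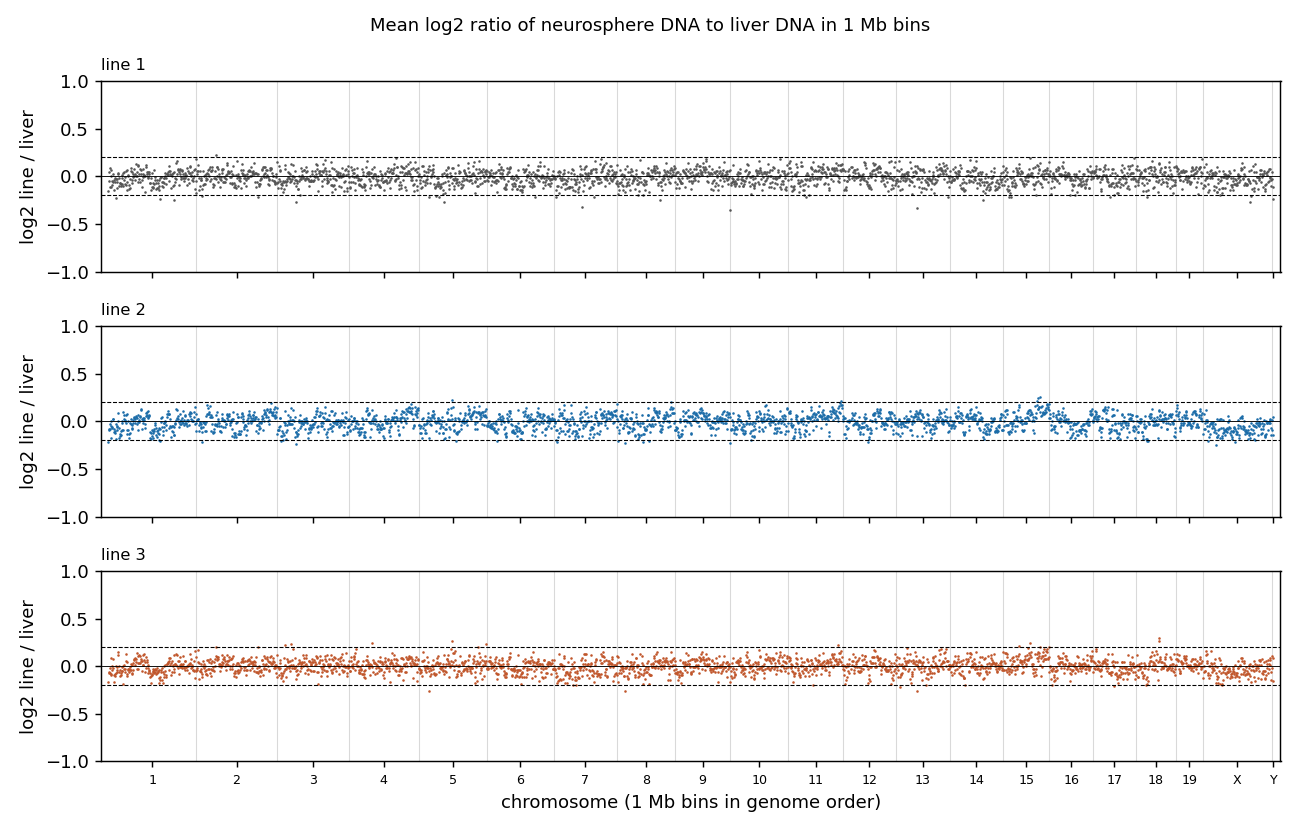
Mean log2 ratio of line DNA to liver DNA in bins of 1 Mb with at least 5 probes, in genome order by chromosome, with 1 panel per line and dashed lines at the call threshold of 0.2 on either side of 0. Bins scatter around 0 in each line, and the distal part of chromosome 15 averages 0.14 in line 2.

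**Figure D2:**
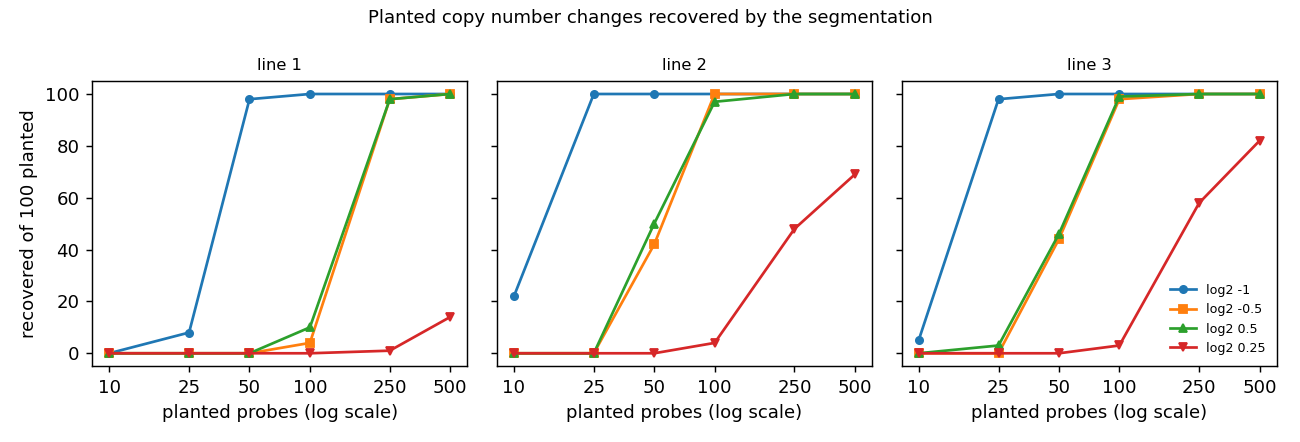
Number of planted changes recovered of 100, by the number of probes planted (log scale), for 4 sizes of change in log2 and for each line. Gains of 0.5 over 100 probes were recovered 10 times in line 1, 97 times in line 2 and 99 times in line 3.

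Whole chromosomes lay close to the liver level, and no chromosome median was 0.2 or more from 0 in any line. Chromosome 15 had the highest mean, 0.034 ± 0.033 (SD, n = 3), with medians of -0.0038, 0.053 and 0.053 in lines 1, 2 and 3. X had a mean of -0.049 ± 0.022 (SD, n = 3) and Y of -0.072 ± 0.015 (SD, n = 3), both below 0 in 3 of 3 lines. The exact sign flip test (2-sided) gave p = 0.25 for X and for Y, the smallest value that 3 lines allow, and p = 0.50 for chromosome 15 (0.525, 0.525 and 0.700 after Benjamini-Hochberg adjustment over 21 chromosomes). Of the 122 Y probes, 100, 110 and 112 were well above background for liver DNA in lines 1, 2 and 3, and 110 for the DNA of each line. Normexp background correction took line 1 past the threshold, with medians of -0.28 on X and -0.32 on Y, and loess took its Y median to -0.21.

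Short stretches differed from liver in lines 2 and 3, the lines with 1 animal number, and among them a region holding Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 regulator Arf. That region on chromosome 4, from 88830688 to 88946623 (9 probes), averaged -0.63 in line 2 (-0.79 to -0.47), -0.54 in line 3 (-0.67 to -0.42) and -0.023 in line 1 (-0.30 to 0.25). The 2 probes named for Cdkn2a itself averaged -0.75 in line 2, -0.64 in line 3 and -0.33 in line 1. On chromosome 6, 10 probes from 77633344 to 77717308 that carry the name of Ctnna2, a catenin of neurons, averaged -0.75 in line 2 (-0.91 to -0.58) and in line 3 (-0.89 to -0.62), and -0.34 in line 1 (-0.55 to -0.12). On chromosome 3, 8 probes from 25262918 to 25370432, some of them named for Nlgn1, a synaptic adhesion protein, and AK075734, averaged 0.52 in line 2 (0.41 to 0.62), 0.60 in line 3 (0.48 to 0.73) and 0.026 in line 1 (-0.090 to 0.14). The mean of lines 2 and 3 differed from line 1 by -0.56 (-0.75 to -0.38) on chromosome 4, by -0.41 (-0.55 to -0.27) on chromosome 6 and by 0.53 (0.39 to 0.68) on chromosome 3. Ctnna2 and Nlgn1 were chosen after their values were seen. Among the segmentation settings run, the regions came out only with a penalty of 2 times log(n) and a minimum of 5 probes together, chosen after the data were seen, which called 0, 8 and 43 regions in lines 1, 2 and 3. Permuted probes gave a mean of 0, 0 and 0.2 calls there. Permuting removes small shifts shared by neighbouring probes, which these arrays had, so it cannot tell how many calls such shifts give. Of the calls, 6 overlapped by at least 50% between lines 2 and 3, and these 3 are those that differed from line 1 by at least 0.3. At that setting, planted losses of -0.5 over 10 probes were recovered 1, 55 and 56 times of 100, so a missing call in line 1 does not show that a change of this size was absent.

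**Figure D3:**
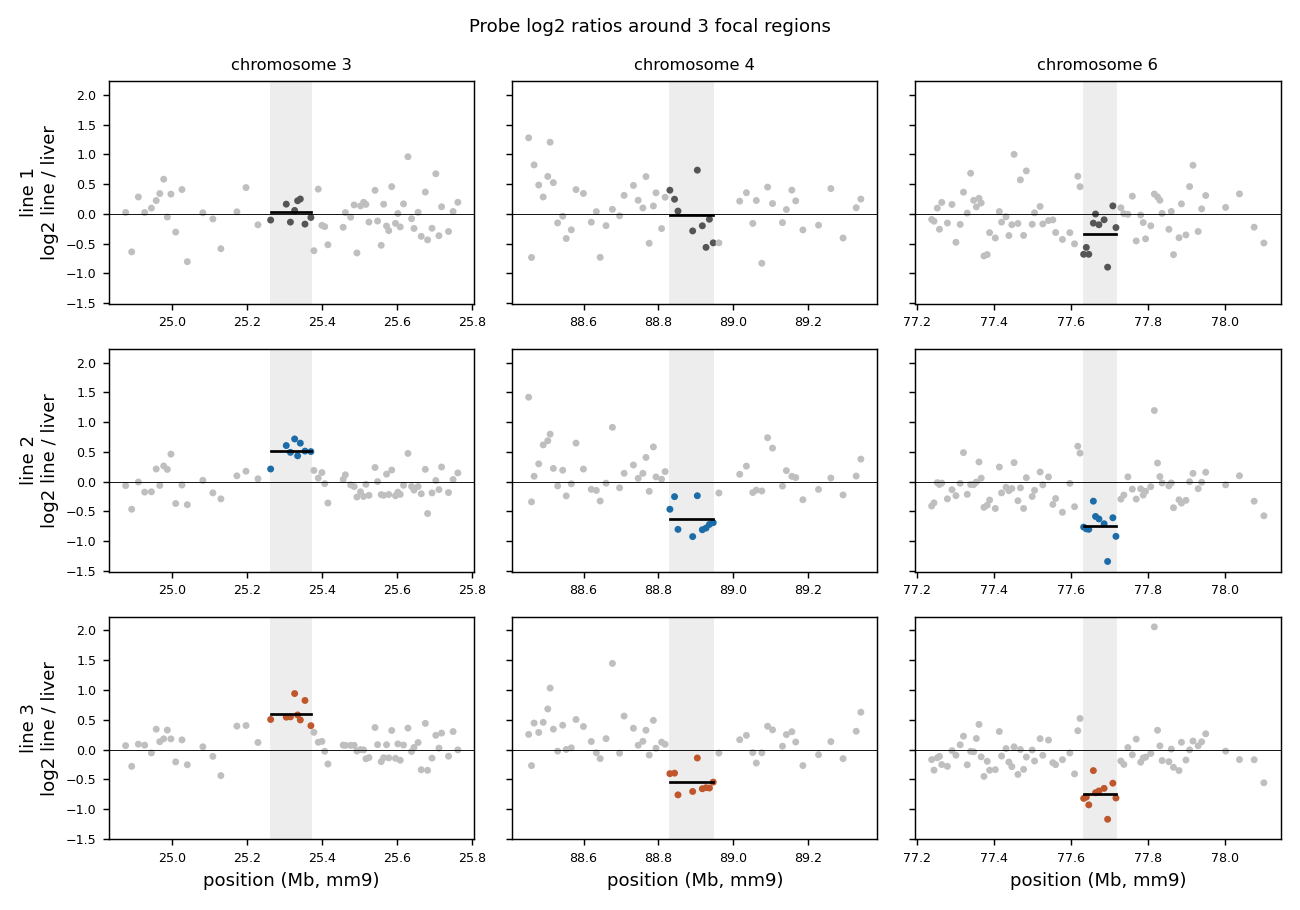
Log2 ratio of line DNA to liver DNA of each probe (points) by position in Mb, for the 3 regions in columns and the 3 lines in rows, with the region shaded, its probes coloured and its mean as a black bar. On chromosome 4 the mean is -0.63 in line 2, -0.54 in line 3 and -0.023 in line 1.

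In windows of 500 kb on each side of a gene, means ran from -0.12 to 0.197 over 28 genes of IGF1R, PI3 kinase, AKT and mTOR and from -0.13 to 0.23 over 16 genes of CSF1R and interleukin 4, with each line counted. Igf1r, the receptor of insulin-like growth factor 1, on chromosome 7 from 75103700 to 75372577, averaged 0.023 ± 0.017 over its 30 probes (SD, n = 3; limma adjusted p = 0.686), and its windows averaged 0.0026, 0.038 and 0.021 in lines 1, 2 and 3. Windows around its ligand Igf1 averaged -0.099, -0.0074 and -0.0059. Windows around Pik3ca, a catalytic subunit of PI3 kinase, averaged -0.052, -0.036 and -0.067. Csf1r, on chromosome 18 from 61270472 to 61285640, had 2 probes with a mean of -0.50 ± 0.12 (SD, n = 3), while its windows of 95 probes averaged 0.022, 0.105 and 0.045. Pdgfra, a growth factor receptor of glial progenitors, on chromosome 5 from 75548298 to 75589956, had window means of 0.060 (-0.074 to 0.19), 0.20 (0.099 to 0.31) and 0.23 (0.069 to 0.39). Trp53 had 2 probes with a mean of 0.40 ± 0.029 (SD, n = 3) and windows of 0.064, 0.16 and 0.14. Egfr windows averaged 0.048, -0.10 and -0.057, and those of Nf1, Rb1, Mdm2, Cdk6 and Met lay between -0.037 and 0.094. Windows around the neighbours of Myc averaged 0.049, 0.065 and 0.13, and those around the neighbours of Cdk4 0.034, 0.13 and 0.087. Cdkn2a windows, of 61 probes, averaged 0.096, 0.045 and 0.10, and hold the 9 probes of the region on chromosome 4. Over the 157 list genes with a window, 2 reached 0.2 in some line, Pdgfra and Csf2rb, and 1 reached -0.2, the Y gene Zfy2. With a penalty of 2 times log(n) and a minimum of 5 probes, 5 list genes lay in called regions, Cdkn2a among them. Csf2rb, a shared receptor chain for several cytokines, lay in a gain of 0.22 over 273 probes on chromosome 15 in line 2. In line 3, Pdgfra lay in a gain of 0.21 over 174 probes, Pik3r1, a regulatory subunit of PI3 kinase, in a gain of 0.20 over 73 probes, and Ret, a receptor tyrosine kinase, in a loss of -0.21 over 77 probes. Windows around Pik3r1 averaged 0.075 (0.012 to 0.14), 0.10 (0.027 to 0.17) and 0.197 (0.11 to 0.28) in lines 1, 2 and 3. Pik3r1 and Ret were chosen after their values were seen.

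**Figure D4:**
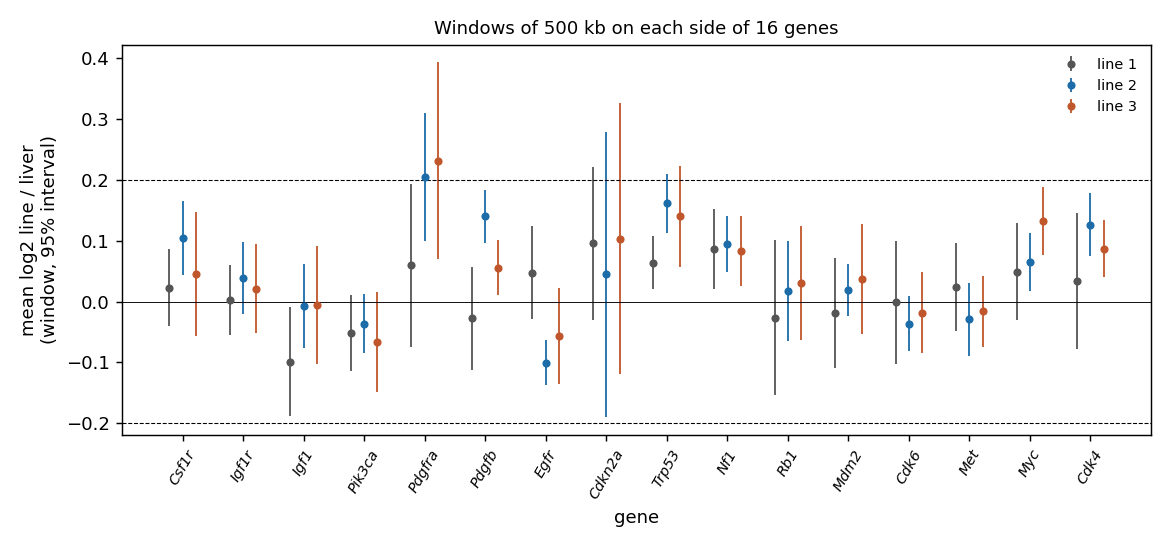
Mean log2 ratio with its 95% interval in windows of 500 kb on each side of 16 genes in the 3 lines, with dashed lines at 0.2 on either side of 0. Myc and Cdk4 are read around their named neighbours, and the Pdgfra windows average 0.060 in line 1, 0.20 in line 2 and 0.23 in line 3.

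Probes named for single genes gave many means away from 0, and windows around the same genes were often near it. Pdgfra averaged 0.28 ± 0.17 (SD, n = 3; limma adjusted p = 0.0178), above 0 in 3 of 3 lines, and missed the threshold without line 3 (mean 0.19, limma adjusted p = 0.0715) and with lines 2 and 3 averaged as 1 animal (0.0780). Pdgfb, a ligand of PDGF receptors, averaged -0.39 ± 0.32 (SD, n = 3; limma adjusted p = 0.0268), with -0.74, -0.095 and -0.34 in lines 1, 2 and 3 and windows of -0.027, 0.14 and 0.056. Its mean was -0.22 without line 1, whose array had the widest spread. Ccnd3, a cyclin of the G1 phase, averaged 0.33 ± 0.13 (SD, n = 3; limma adjusted p = 0.00678) with windows of 0.070, 0.14 and 0.056. Il4ra, a receptor chain for interleukin 4, averaged 0.31 ± 0.14 (SD, n = 3; limma adjusted p = 0.00872) with windows of -0.00023, 0.049 and -0.088. Among genes past the limma threshold with 1 sign in all lines, Cidea, a lipid droplet protein, had the highest mean, 0.60 over 3 probes. Its windows averaged 0.053, 0.029 and 0.019, and Thumpd3 averaged 0.54 over 3 probes. Low means included Rars, the arginyl-tRNA synthetase, at -0.54 and Dgat2, an enzyme of triglyceride synthesis, at -0.53, over 3 probes each, and Kif3a, a kinesin subunit needed for cilia, at -0.47 over 4 probes. Of 9430 genes, 2276 passed limma's adjusted threshold, 1339 above and 937 below 0, and 3757 had an unadjusted p under 0.05. After the probes were reassigned to genes, a median of 2074.5 passed (1893 to 2274 in 20 draws). The count was 1064 without line 2, 1258 without line 3 and 731 with lines 2 and 3 averaged as 1 animal. The split was 801 above and 1034 below 0 in the authors' value table and 1097 above and 1172 below after correction for local gene number.

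Over all 9430 genes tested, 2276 passed limma, and a median of 2074.5 did so after probes were reassigned to genes. List members that passed are to be read against that share, and do not by themselves mark a copy number change. None of the 9 gene lists passed the threshold with fry of limma, and 2 had an unadjusted p under 0.05. The lowest was the list of glioma drivers and lineage genes (fry adjusted p = 0.116 from limma, median 0.080 over 15 genes), where Idh2, a mitochondrial isocitrate dehydrogenase, passed above 0, 14 genes did not pass, and 1 passed adjusted over the list alone. That list passed with lines 2 and 3 averaged as 1 animal (fry adjusted p = 0.0310 from limma) and with gene medians (0.0183), and its adjusted p was 0.0635 to 0.442 under the other settings. The other was cell cycle and p53 (fry adjusted p = 0.167 from limma), where Ccnd3 and the p53 inhibitor Mdm4 passed limma above 0, 3 of 5 genes did not pass, and 2 passed adjusted over the list alone. Of 24 genes of IGF1R, PI3 kinase, AKT and mTOR, Pik3cd passed above and Rps6kb1 below 0, 22 did not pass, and limma gave 0 adjusted over the list alone and 5 at an unadjusted p under 0.05. The CSF1R and interleukin 4 list had 10 genes tested, of which Il4ra, Stat6 and Il34, a ligand of CSF1R, passed above 0 and F13a1 below, and 4 passed adjusted over the list alone. Of 21 receptor tyrosine kinase and ligand genes, Pdgfra passed above 0 and Pdgfb and Erbb3 below, and 3 passed adjusted over the list alone. The mismatch repair gene Msh3 and the damage kinase Atm passed below 0 among 11 DNA repair genes, with 2 adjusted over the list alone. Of 8 drug efflux transporters, Abcc2 passed above and Abcc5 below 0, with 2 adjusted over the list alone. The RAS and MAPK list, with 9 genes tested, had a median of 0.045 (fry adjusted p = 0.285 from limma). Usp9y passed below 0 among 9 sex chromosome genes, where limma gave 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. Without line 2 and without line 3, Il34, F13a1, Msh3, Abcc2, Abcc5, Mdm4 and Usp9y missed the threshold (limma adjusted p from 0.0609 to 0.281), Pdgfra missed it without line 3, and Pik3cd and Rps6kb1 missed it with any 1 line left out (0.0513 to 0.164). With lines 2 and 3 averaged as 1 animal, all of these genes and Atm missed it (limma adjusted p from 0.0502 to 0.173). Idh2, Ccnd3, Il4ra, Stat6, Pdgfb and Erbb3 passed in that fit (0.0365 to 0.0457). With the main settings, no list member lay in a called region, since there were 0 regions.

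The lines resembled each other in their small deviations. Over 2388 bins of 1 Mb, r was 0.702 between lines 1 and 2, 0.635 between lines 1 and 3 and 0.722 between lines 2 and 3. These correlations are across bins of the genome, which are not independent replicates. Probes shuffled along the genome together on all arrays gave mean r of 0.698, 0.644 and 0.819. Covariances were 0.00437, 0.00355 and 0.00425, against 0.00121, 0.00119 and 0.00096 with probes shuffled. A simulated liver reference shared by lines 2 and 3, with as much variance as each array's own noise, gave r = 0.499. That value follows from the variance chosen, so it does not measure the part of the liver in the r of these lines. Part of the r of lines 2 and 3 may not be separated from the shared liver label.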

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

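The penalty of 2 times log(n) with a minimum of 5 probes, the gene number correction and the windows were chosen only after the result was seen. Of 174 values under other settings, 132 stayed the same, 40 moved, 2 passed the threshold anew and 0 reversed. Some of the 132 could not have moved, so the tally overstates how stable the results are. Among these were values with saturated probes left out and correlations after another centring. So were counts of 0 under a higher call threshold, and the chromosome count with 1 line left out. A count stayed the same when within a set factor of the first count, which need not mean the same genes. An adjusted p did so on its side of the threshold, and a correlation or median within its spread over pairs or lines. Calls went from 0 to 2, 1 and 1 regions under normexp in lines 1, 2 and 3, to 1 in line 1 under loess, to 1 in lines 1 and 3 with the authors' value table, to 2 in line 2 at a threshold of 0.1, to 1 in line 3 at a penalty of 5, and to 8 and 43 in lines 2 and 3 at a penalty of 2 with at least 5 probes. Chromosomes past 0.2 went from 0 to 2 under normexp and 1 under loess. Genes past limma's threshold went from 2276 to 4768 of 21106 with at least 1 probe, 746 of 2759 with at least 10 probes, 1023 of 2534 bins of 1 Mb, and 731 with the lines of 1 animal averaged. Leaving out 1 line gave 1064 to 3193, lowest without line 2 and highest without line 1. The fit without line 1 holds only lines 2 and 3, so its 3193 genes rest on 1 animal number and 1 liver label. Under normexp 2222 genes passed, of which 1129 were among the 2276. Lists past the threshold went from 0 to 1 with gene medians and with 2 animals, each time glioma drivers and lineage (fry adjusted p = 0.0183 and 0.0310 from limma, 0.0635 to 0.442 under its other settings). List members in called regions went from 0 to 16 under normexp, 7 under loess and 7 with the value table (those 7 on Y), 2 at a threshold of 0.1 and 5 at the penalty of 2 with at least 5 probes, and 3 had windows at or past 0.2. Correlations over bins moved to 0.891 for lines 2 and 3 with the value table, 0.611 for lines 1 and 2 after gene number correction, 0.656 (lines 1 and 2) and 0.771 (lines 2 and 3) in bins of 100 kb, and 0.670 (lines 2 and 3) in bins of 5 Mb. Lines shared 1556626 called base pairs at the penalty of 2 with at least 5 probes. Normexp moved X to -0.28, -0.17 and -0.10 and Y to -0.32, -0.19 and -0.10 in lines 1, 2 and 3, and leaving out dim probes moved X to -0.058 and Y to -0.13 in line 1. Apart from fewer or more genes and samples tested, the cause was not tested. Leaving out saturated probes changed nothing, since there were 0. No paired analysis was possible because there is only 1 group. The animal as a random block could not be fitted, since 0 genes gave an estimate of the correlation. Array 1, with 96.3% of liver probes well above background and the widest spread, limits what line 1 can show.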

Other observations

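Tests of the focal regions against effects shared by the arrays, against the liver signal and with line 3 left out of the choice were chosen only after the result was seen, as were the comparisons within a dye and the windows. Of 6 comparisons of arrays within a dye, line DNA of line 2 against line 1 gave 3 called regions, and the other 5 gave 0, those of liver DNA among them. The widest was a stretch of chromosome 9 from 104253345 to 106034972 (142 probes), which holds Col6a4, Col6a5 and Col6a6, collagen VI genes, and Pik3r4, a regulatory subunit of a PI3 kinase. Line DNA was higher there than in line 1 by 0.23 in line 2 (0.16 to 0.31) and by 0.20 in line 3 (0.13 to 0.27), and liver DNA by 0.20 (0.11 to 0.28) and 0.22 (0.13 to 0.31). The ratios of line to liver were -0.058, -0.0078 and -0.062 in lines 1, 2 and 3. At Cyp2b9 and Cyp2b13, cytochrome genes on chromosome 7 from 26743426 to 26981899 (10 probes), line DNA was higher by 0.91 (-0.0022 to 1.82) in line 2 and 0.88 (0.041 to 1.72) in line 3, and liver DNA by 0.75 (-0.18 to 1.68) and 0.71 (-0.21 to 1.63), with 3 of these 4 intervals holding 0. On chromosome 9 from 103369918 to 103460933 (10 probes, Bfsp2 and Tmem108) line DNA was higher by 0.68 (-0.445 to 1.80) in line 2 and 0.59 (-0.57 to 1.75) in line 3, and liver DNA by 0.64 (-0.43 to 1.72) and 0.55 (-0.53 to 1.64), with ratios of 0.051, 0.098 and 0.10 in lines 1, 2 and 3. Both dyes of an array share its spots and, by the labels, its animal number, and no explanation was tested.

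In 3 further regions, called in both lines 2 and 3 with a penalty of 2 times log(n) and a minimum of 5 probes, line 1 lay at a like level. One on chromosome 15 from 8575756 to 8863277, with probes named for Slc1a3, a glutamate transporter of astrocytes, averaged 0.35, 0.385 and 0.48 in lines 1, 2 and 3. One on chromosome 12 from 80775437 to 81270858, with Actn1 and Rad51l1, averaged 0.24, 0.29 and 0.32. One on chromosome 4 from 88351726 to 88817991, with Mtap, an enzyme of methionine salvage, averaged 0.21, 0.22 and 0.27, beside the Cdkn2a region. A stretch of chromosome 18 from 54073534 to 56201843, with Csnk1g3 and Zfp608, averaged 0.15, 0.12 and 0.29. These genes were chosen after their values were seen.

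In the 3 focal regions, low or high in lines 2 and 3, probe and dye effects shared by the arrays stay open in part. An effect of the same size on all 3 arrays would cancel when arrays are compared within a dye. Line DNA of lines 2 and 3 less that of line 1 was 0.57 (0.47 to 0.68) on chromosome 3. It was -0.54 (-0.62 to -0.45) on chromosome 4 and -0.40 (-0.59 to -0.20) on chromosome 6. These values argue against it as the whole cause, though the regions were picked for their difference from line 1. A part of it, or an effect of arrays 2 and 3 alone, stays open. The 6 regions were called without line 1, and 3 of them differed from it by over 0.3 with intervals leaving out 0. The focal regions were picked for that difference, and the bound was set with the values known, so this count decides nothing. In the other 3 regions line 1 lay within 0.2 of the mean of lines 2 and 3. Line 1 was also low at Ctnna2 (-0.34). Its 2 probes named for Cdkn2a averaged -0.33 but lay apart, at -0.56 and -0.091. All 9 probes of that region averaged -0.023 in line 1 (-0.30 to 0.25). The shared liver reference is argued against as the whole cause by the liver signal of arrays 2 and 3 less that of array 1, 0.0512 on chromosome 3 (-0.11 to 0.21), 0.040 on chromosome 4 (-0.13 to 0.21) and 0.030 on chromosome 6 (-0.13 to 0.19), where a liver level high enough to give the ratio's difference of -0.41 lies outside the interval but a part of it does not. Noise stays open in part: the rank of each region in the difference from line 1 (at most 0.353 runs in 1000 as far) decides nothing for regions picked by that difference. Of 7 regions that differed between lines 1 and 2 by at least 0.2 (5 by at least 0.3), chosen without line 3, 3 lay at the focal places, with at most 0.0353 runs in 1000 of line 3 as far, and the other 4 had 7.06 at Rusc2, 490 at Gphn, 787 at Arc and 900 at Prdm16, with line 3 at 0.40 (-0.39 to 1.18), 0.0022, -0.051 and -0.068. Line 3 is not independent of line 2: they share an animal number and a liver label, and their probes correlated at 0.814. This ranking speaks only to noise of arrays 1 and 2 alone, and cannot test effects that lines 2 and 3 share. A loss or gain in tumour cells is a hypothesis that stays among the open explanations. Every difference here rests on array 1, whose ratios had the widest spread. In liver DNA, the spread of arrays 2 and 3 less array 1 was 0.25 and 0.28, against 0.145 for array 2 less array 3. In line DNA the same spreads were 0.13 and 0.19, against 0.15.

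Many genes passed limma across the 3 lines. Probe and dye effects shared by the arrays could account for most of the count, since reassigned probes gave a median of 2074.5 genes against 2276. Means of odd and even probes correlated at 0.187 over 7283 genes with at least 4 probes, against -0.0036 after reassignment, so probes of a gene shared some signal. Among 1531 genes past the threshold the correlation was 0.587, above the 0.5 set beforehand as the mark of copy number. Genes that passed after reassignment gave a median of 0.465 and up to 0.528, so that mark can be reached by choosing genes this way and does not point to copy number. The 0.587 lay above all 20 draws, so probes of these genes shared some signal beyond the choice. Whether copy number or another regional effect gave the shared part stays open.

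Some regions were shifted by a small amount in all 3 lines, and these shifts were set against marker genes of the tissues compared. Windows of 250 kb on each side of 23 neural progenitor genes had a median of 0.077 and those of 36 hepatocyte genes 0.0105, a difference of 0.066 in the mean of the 3 lines (permutation p = 0.0024, 2-sided, 10000 draws of genes matched on local GC, 0.0047 after Benjamini-Hochberg adjustment over 9 such tests). By line the difference was 0.034, 0.0071 and 0.072 (permutation p = 0.173, 0.726 and 0.0026, adjusted 0.194, 0.726 and 0.0047), so lines 1 and 2 missed the threshold on their own, and requiring each line was decided after these values were seen. After correction for local GC, 0.675 of the difference was left, between the bounds of 0.5 and 0.8 set beforehand, and at 0.045 it stayed past the threshold (permutation p = 0.0314 matched on GC and 0.0104 matched on gene number, adjusted 0.0404 and 0.0156), as did the 0.067 after correction for gene number (adjusted 0.0040 and 0.0047) and the uncorrected difference matched on gene number (adjusted 0.0040). Local GC may account for part of it, and a difference between neural cells and liver in replication or chromatin stays open, since lines 1 and 2 alone did not pass.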
